A study of Homo sapiens with 8 samples.

How the data were processed

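Human tracheal epithelial cells in primary culture were grown at an air-liquid interface, in which the upper face of a confluent layer is exposed to air and the cells are fed from below. RNA was taken at day 21 from 4 untreated samples and from 4 samples given interleukin-13 (IL-13) at 50 ng/ml from day -2 onward, per the labels' protocols. Total RNA was amplified and labelled with biotin using an Illumina kit, per the labels' protocols, and hybridised to an array with 1 colour. No label says whether the 4 samples of a group came from separate donors or cultures, so the p-values measure only the spread between these samples, which may be technical.

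A single table of 23629 probes and 8 arrays was used, and all 8 of its columns belong to the study's samples. The deposited values are on the log2 scale, as judged from their range of 5.02 to 14.82 and not from any statement in the sources. Of the values on an array, 68.6% (16219 distinct values, matched exactly as deposited, with no rounding or tolerance) were shared by all 8 arrays, and the 8 medians lay between 6.2975 and 6.2982, which is the pattern that quantile normalization by the authors would leave. Limma is named in the submitters' processing notes, with no version and no role. The background correction and the array model are not given in the sources used here. The lowest maximum of any probe over the 8 arrays was 5.84, a sharp edge, while 23.9% of all values lay below it. The probes therefore appear to have been kept for reaching a minimum on at least 1 array. Near this edge, 782 of the 1820 probes whose maximum lay within 0.05 of it (43.0%) had that maximum on an IL-13 array. No detection p-values or control spots were used here, so whether a dim probe stood above background was not assessed. The number of arrays limits the precision.

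The rows are identified by Illumina probe IDs alone. The table does not pair them with genes, and none (0) of the IDs occurs in the RefSeq gene table of assembly GRCh38.p14 that was at hand. Probes are therefore counted as probes, and no gene is named. Several probes can read 1 gene, so the counts are not counts of genes. The 21 gene lists fixed before the data were examined (mucin, ciliated, basal and other cell markers among them), and the rule for named genes, could not be applied. The planned counts of genes became counts of probes. In place of the rule for genes, the 2 largest rises and the 2 largest falls are given by probe ID, among probes past the threshold whose 4 values in each group did not overlap.

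From the deposited log2 values, a linear model with an intercept and an IL-13 term was fitted to each probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, not robust, all probes, all arrays at equal weight). P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 23629 probes. A probe was called at an adjusted p under 0.05, and changes of 2-fold or more are those with an absolute log2 difference of at least 1. The prior SD was 0.142 with 2.87 prior degrees of freedom. Plots were drawn with matplotlib 3.10.9. On simulated data with each probe's own spread and 200 of 23629 probes changed, the fit for IL-13 against untreated called 29 of 67 probes changed by 0.5 on the log2 scale (43.3%). It called 52 of 67 changed by 1 (77.6%) and all 66 of 66 changed by 2. In that simulation 4 unchanged probes were called, 2.65% of its calls. It had few changed probes and gave a probe the same spread in both groups, so these shares are not those of the real fit.

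The groups share replicate numbers 1 to 4, and the labels do not say what a number marks. The numbers were not taken as pairs, and the fit with them as a block was kept as an alternative. The other alternatives chosen before the data were examined were an intensity trend with a robust prior, quantile normalization, median centring, cyclic loess, removal of the dimmest 25% or 50% of probes, array weights, and leaving out each array in turn. No slide or scan batch is given by the labels, so batches were not tested. The sample titles number all untreated samples before all IL-13 samples, and the labels do not say what these numbers mark. A batch that followed this order could not be told apart from IL-13.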

Results

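The effect of IL-13, a cytokine of type 2 immunity known to drive mucous cell differentiation in airway epithelium, was examined on the transcriptome of human tracheal epithelial cells after 21 days at an air-liquid interface. There were 4 untreated arrays and 4 arrays of cells given 50 ng/ml of IL-13 from day -2 onward. Each held log2 signals for 23629 probes. Arrays of the same group correlated more closely than arrays of different groups. Pearson's r over probes was 0.982 to 0.995 between untreated arrays and 0.968 to 0.985 between IL-13 arrays, against 0.928 to 0.952 between an untreated and an IL-13 array. Probes are not independent replicates, so these values only describe the arrays. The first principal component held 63.8% of the variance and separated the groups, with untreated arrays at -43.8 to -37.3 and IL-13 arrays at 34.4 to 46.4.

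**Figure D1:**
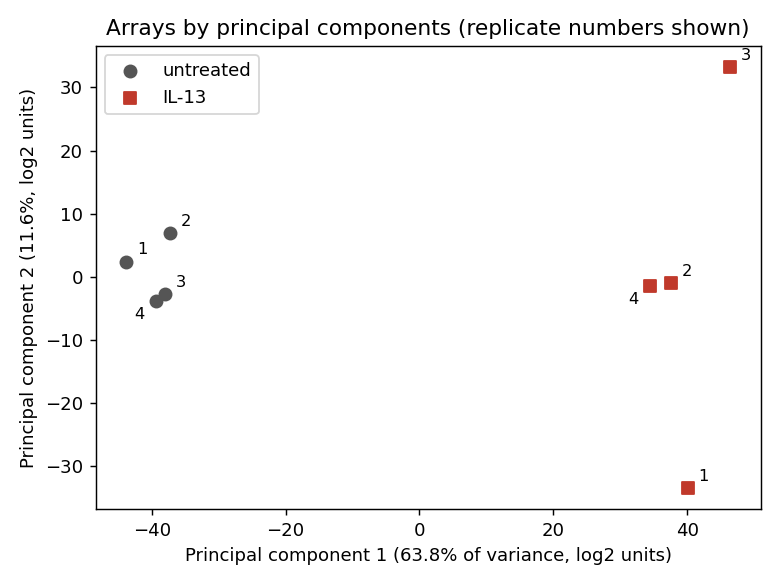
Principal components 1 and 2 of the 8 arrays in log2 units, with untreated arrays as grey circles and IL-13 arrays as red squares. Component 1 (63.8% of the variance) separates the groups, and component 2 (11.6%) sets IL-13 replicate 3 (33.2) apart from IL-13 replicate 1 (-33.5).

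Between the groups 3277 probes differed in signal, 13.9% of those measured (limma with Benjamini-Hochberg adjustment, adjusted p under 0.05, n = 4 per group). The signal rose at 1458 of these probes and fell at 1819. All samples were taken at day 21, so a rise or a fall is a difference between the groups and not a change followed over time. The median size was 0.74 on the log2 scale for the rises and 0.67 for the falls. Among changes of 2-fold or more, 500 probes rose and 451 fell, and at 943 of these 951 probes the 4 IL-13 values did not overlap the 4 untreated values. Over all probes, 4612 (19.5%) had no overlap between the groups, where chance alone gives 2.86%, or about 675 probes. The median change over all 23629 probes was -0.003. Without untreated replicate 3 the falls numbered 1188 and the rises 1025, and without untreated replicate 4 they numbered 1224 and 1027.

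The largest changes were mostly rises. At 8-fold or more, 72 probes rose and 36 fell, and at 16-fold or more 36 rose and 14 fell. Rises of at least 64-fold were found at 10 probes, against 1 fall of that size, at ILMN_1774250, where the log2 change was -7.67 with all arrays and -8.73 without IL-13 replicate 1. The counts of 8-fold changes moved little when single arrays were left out, with 70 to 76 rises and 27 to 40 falls.

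**Figure D2:**
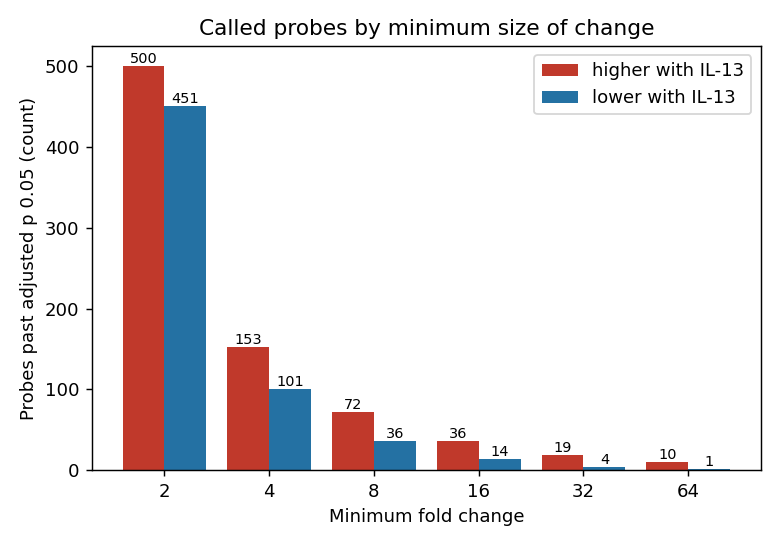
Number of probes past an adjusted p of 0.05 at each minimum fold change, for probes higher (red) or lower (blue) with IL-13. The bars are close at 2-fold (500 and 451 probes) and part at larger sizes (72 and 36 at 8-fold, 36 and 14 at 16-fold).

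The 2 probes with the largest measured rises went from the dim end of the arrays to near the top of the scale. The signal of ILMN_1753449 was 5.64 ± 0.07 (SD, n = 4) in untreated cells and 14.39 ± 0.22 (SD, n = 4) with IL-13, a log2 difference of 8.75 (SE 0.11, adjusted p = 5.27e-10, limma). That of ILMN_1659601 was 5.79 ± 0.07 untreated and 14.30 ± 0.15 with IL-13, a log2 difference of 8.51 (SE 0.09, adjusted p = 2.36e-10, limma). Both untreated means lay below 5.84, the level that every probe of the table reached on at least 1 array. Whether they stood above background was not assessed, so both differences are those of the measured signals and understate the change if the untreated signals were background.

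The 2 largest falls began among the brightest signals, and their IL-13 values had the wider SDs. The probe ILMN_1774250 had a signal of 14.79 ± 0.02 (SD, n = 4) in untreated cells and 7.11 ± 2.11 with IL-13, and so fell by 7.67 on the log2 scale (SE 0.87, adjusted p = 0.00055, limma). Without IL-13 replicate 1 it fell by 8.73. Its untreated values sat at 14.82, the highest value on each of the 8 arrays, or just under it, so its fall too is that of the measured signals. All of them but that of untreated replicate 4 were equal, as can occur where arrays share most of their values. The untreated SD of 0.02 therefore need not measure the spread between the samples. The probe ILMN_1679666 went from 14.22 ± 0.14 to 8.74 ± 0.86 and fell by 5.48 (SE 0.36, adjusted p = 2.29e-05, limma).

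Some called probes crossed the middle of the signal distribution. In all, 66 called rises lay below the median of all values (6.30) in untreated cells and above the upper quartile (7.76) with IL-13. The opposite order, above the upper quartile in untreated cells and below the median with IL-13, was found at 43 called falls. Of the 72 rises of 8-fold or more, 36 (50.0%) lay below the median in untreated cells. Of the 36 falls of that size, 15 (41.7%) lay below it with IL-13. The brighter group of these probes had a median signal of 10.76 for the rises and 10.60 for the falls.

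Calls were more frequent among brighter probes. In the dimmest quartile by mean signal, 2.20% of 5908 probes were called. The quartiles are those of the mean over all 8 arrays, so a large change itself moves a probe out of the dimmest one. The share was 9.73% in the next quartile, 20.6% in the third and 23.0% in the brightest. Falls outnumbered rises most clearly among dim probes, with 95 falls and 35 rises in the dimmest quartile and 367 falls and 208 rises in the next. In the third there were 643 falls and 572 rises, and in the brightest 714 falls and 643 rises. Among changes of 2-fold or more there were 26 falls and 8 rises in the second quartile, 180 falls and 166 rises in the third, and 245 falls and 326 rises in the brightest.

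**Figure D3:**
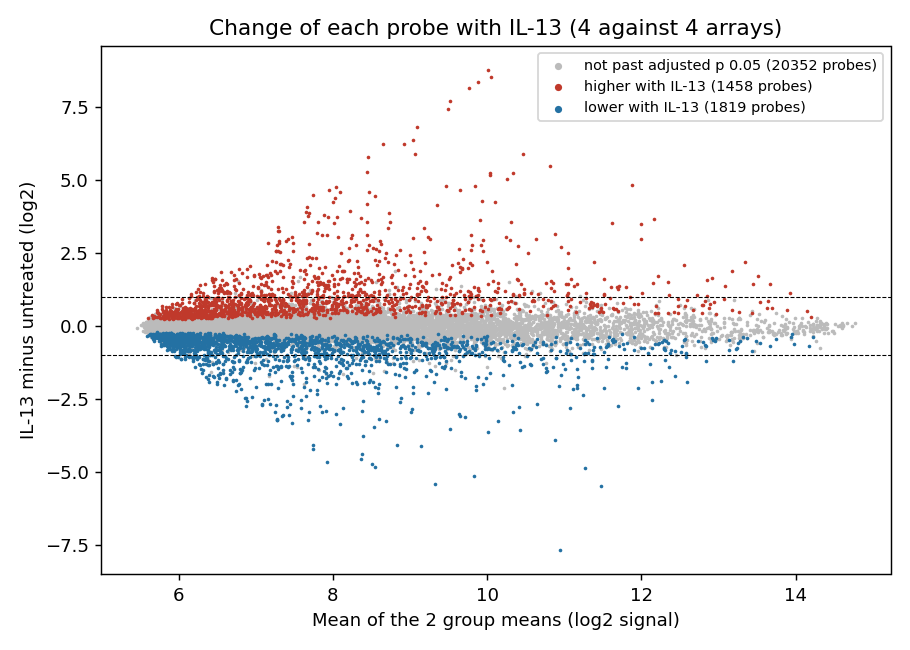
Difference between the IL-13 and untreated group means of each probe (log2) against the mean of both (log2 signal), with called rises in red (1458), called falls in blue (1819) and other probes in grey (20352). Dashed lines mark a 2-fold change, and the highest points are rises of up to 8.75.

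The 4 IL-13 arrays showed the response at nearly the same strength. For each, its change over the 2-fold probes called without it was regressed on the mean change of the other 3, with the baselines taken from different untreated arrays. The slopes were 0.96, 0.97, 0.99 and 0.97 for rises and 0.94, 1.01, 1.08 and 0.94 for falls, in order of replicate number. A slope near 1 stands for a response about as strong as that of the other arrays. The probes were chosen for large changes in those other arrays, which can pull a slope below 1. The root mean square distance of an array from the mean of the other 3 of its group was 0.293 ± 0.057 (SD, n = 4) with IL-13 and 0.216 ± 0.053 (SD, n = 4) without it. This difference was not past the threshold in an exact permutation test of the 8 arrays (two-sided p = 0.14, the smallest possible being 0.029); distances within a group share arrays. The median SD of a probe was 0.161 with IL-13 and 0.115 untreated.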

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

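The tests of spread along the response and at the dim end, the tests of scaling between arrays and of the floor at 8-fold, the counts of splits and the setting without the 3 arrays of lowest weight were chosen only after the result was seen.

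One probe stood out in both groups by the gap of a single array to the others, among 22 sets of 4 values examined, where chance marks about 1 set in 20. ILMN_1774250, the probe with the largest fall, had a signal of 10.28 in IL-13 replicate 1, and its gap to the nearest array divided by the range of the 4 values was 0.93. Its log2 change was -8.73 without that array and -7.67 with it. In untreated replicate 4 it had a signal of 14.82, the highest of the table, and the other 3 untreated arrays gave a single lower value, an SD of 0.02 in all. With 3 equal values this ratio is 1 whatever the size of the gap. The rate of 1 set in 20 therefore does not apply to the untreated set, and its flag does not mark an unusual array.

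Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many called probes, for rises (1458), falls (1819), 2-fold rises (500) and 2-fold falls (451). The highest other split gave 0 probes in limma in each case. The other splits mix the groups, so the IL-13 difference adds to their spread, which works against calls. An uneven mix also keeps a part of that difference between its sides, which can raise its count. The counts of the other splits therefore do not measure chance. At an unadjusted p under 0.05 the real split had 6115 probes and the 34 others 159 to 2846, where about 1181 are expected without any difference.

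Large rises outnumbered large falls by 2 to 1 at 8-fold. Scaling between arrays, as far as cyclic loess removes it, was argued against as the whole cause, since the ratio after it was 2.26 (1.92 to 2.88 with single arrays left out), while quantile normalization and median centring left both counts at 72 and 36 and so tested nothing here. A floor of the dim end, which would shorten changes that reach it, was argued against only as the whole cause: with both group means above the median of all values, 36 probes rose and 21 fell by 8-fold or more, a ratio of 1.71 (1.5 to 2 with single arrays left out). At 4-fold these counts were 97 and 62, a ratio of 1.56 (1.42 to 1.77 with single arrays left out), against 153 and 101 over all probes, and a part of the excess at 8-fold stays open to the floor. A biological difference, in which a small set of transcripts is strongly higher in the IL-13 samples, may remain as a hypothesis. It was not tested, since the probes are not paired with genes. Total RNA of a sample also does not separate changes within cells from changes in the mix of cells.

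Among all called probes the order was the opposite, with 1819 falls and 1458 rises. Unaligned dim ends of the arrays were argued against as the whole cause, since quantile normalization left a ratio of 1.21 (1.09 to 1.31 with single arrays left out). The excess was smaller after cyclic loess (1551 rises and 1738 falls, a ratio of 1.12) and without the dimmest 50% of probes (1209 and 1367, a ratio of 1.13), so scaling and dim probes remain open for part of it. It also depended on the arrays used: without the 3 arrays of lowest weight (untreated replicate 2, IL-13 replicates 1 and 3) there were 1361 rises and 1385 falls, a ratio of 1.02, while singly the ratio was 1.35 without untreated replicate 2 and 1.11 and 1.12 without IL-13 replicates 1 and 3. A contribution of the IL-13 arrays is a candidate explanation that stays open, as does a biological one, and untreated replicate 2 taken alone went the other way. The 3 arrays of lowest weight also had the lowest lower quartiles of signal. These were 5.82 and 5.83 for IL-13 replicates 1 and 3 and 5.85 for untreated replicate 2, against 5.86 on the others. A low dim end would add falls in an IL-13 array and rises in an untreated one, so unaligned dim ends stay open for a part.

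The IL-13 arrays lay further apart than the untreated arrays, with a median log2 variance ratio of 1.06. Unequal strength of a shared response between the IL-13 arrays was argued against: of the squared difference between any 2 of them, at most 1.63% lay along the response measured in the other 2. The test does not cover arrays that differ in which probes responded. Noise over the whole array remains open: the ratio was 0.81 in the dimmest quartile of probes, where few were called (0.36 to 1.39 with single arrays left out). It was 1.21 in the second quartile, 0.90 in the third and 1.35 in the brightest. The lower quartiles of signal of the IL-13 arrays ran from 5.82 to 5.86. Such unaligned dim ends would also widen the spread at dim probes, and the test does not tell them from noise. At probes with a change of 2-fold or more the ratio was 0.51, against 1.07 at the others. A chance difference of a few arrays also remains open, at an exact permutation p of 0.14.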

How the results depend on the processing

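No called probe changed sign, among the probes each setting tested, under any of 17 alternatives. Of these, 16 were chosen before the data were examined and 1, leaving out the 3 arrays of lowest weight, afterwards. The replicate block, the trend with a robust prior and the removal of dim probes leave the fitted change as it is. They could not turn a sign, and median centring hardly could. Leaving out or weighting arrays could not turn a sign either where the values of the groups did not overlap. That held for 943 of the 951 called changes of 2-fold or more. The counts of rises, 2-fold rises and 2-fold falls stayed within 1.5 times their values throughout. All falls numbered 1819, and 1188 to 1922 with single arrays left out; the lowest count came without untreated replicate 3, and the cause was not tested. With the replicate block the counts were 1056 rises and 1276 falls, and 490 and 443 at 2-fold, and the numbers were not taken to pair the arrays. Deviations from the group means of same-numbered arrays correlated at -0.16, -0.24, -0.03 and 0.15 over probes, and the closest partner had the same number for replicate 4 alone. Array weights gave the most calls, 1881 rises and 2338 falls. Of the 3277 calls, 1975 (60.3%) were made again in each of the 8 fits that left out an array. Of the 951 calls of 2-fold or more, 889 (93.5%) were, and 855 held in all 15 alternatives that tested every probe. The 4 probes named stayed past the threshold in every alternative, with adjusted p (limma) from 1.74e-14 to 0.0031. The planned mean over probes of a gene, the gene list tests and their alternatives were not run, for want of gene names, and the offset for linear values was not run because the values are on a log scale. In the simulation, with 200 probes changed, 29 of 67 changes of 0.5 on the log2 scale were recovered. The data had 3277 calls, which loosens the adjusted threshold, so this share does not measure what the real fit missed. A probe that was not called is still not shown to be unchanged, and at dim probes no detection value bounds the signal.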
